A study of Caenorhabditis elegans with 2 samples.

How the data were processed

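Chromatin bound by eGFP-tagged LSY-2 was measured by ChIP-seq in whole L1 larvae of both sexes, in 2 biological replicates of 1 group, per the labels. The labels give a size range of 150 to 350 without a unit. The authors deposited peak lists on the ce11 and ce10 builds: a list for each replicate, a list for both replicates pooled, and an IDR-thresholded list. Per the text listings deposited with the lists, each was called against a control alignment, and the IDR list came from the pooled list and both replicate lists. The aligner, the peak caller, their versions and the IDR cut-off are not given in the sources used here. Tested on the values, the IDR list equals the 4218 pooled peaks with the highest signal.

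The deposited signal of each peak is the authors' own value, whose statistic is not given in the sources used here, and it served only to rank and describe peaks. Its level differed between lists (median 8.52 in replicate 1, 7.84 in replicate 2 and 13.9 in the pool), so signals were set side by side and not tested. The deposited −log10 (q value) of each peak, a unit taken from the narrowPeak format, was at its ceiling for 100% of IDR peaks and separated none of them. Each list before IDR holds exactly 30000 peaks, which sets its length. The depth of the samples is unknown, since the lists hold no read counts, and intervals of shares cover the counting of peaks or genes only.

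Positions were counted from 1 on ce11 and matched to the Ensembl release 115 annotation and the genome sequence of the same assembly, without the mitochondrial genome. No coordinates were converted between builds, and ce10 was used for counts, overlaps and correlations alone. A gene had a promoter peak when a summit lay from 1000 bp upstream to 200 bp downstream of any of its annotated transcript starts. A replicate's signal at an IDR peak was that of its nearest summit within 200 bp.

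Replicate overlap needed 1 bp between intervals. Gene lists were compared with all other protein-coding genes (microRNA genes with all genes) by two-sided Fisher's exact tests, with Benjamini-Hochberg adjustment over the 28 lists. Positional tests used 1000 circular shifts of the summits along each chromosome with seed 7. Under shifts, a list's statistic was its share divided by that of the other genes. Chromosome tests were two-sided exact binomial tests, with Benjamini-Hochberg adjustment over the 6 chromosomes where all were compared. Sequence tests compared the presence of each 6-mer with starts within 50 bp of the summit and in an equal number of start positions 300 bp away. Adjusted p under 0.05 passed, and intervals are 95% exact (Clopper-Pearson). Random genes for lsy-2 came from X, its own chromosome, although the plan named autosomes.

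The groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. Named were genes with the summit of a top 20 peak in their promoter window, up to 4 members with the strongest peaks from each list, and always lsy-2, unc-119, lsy-6, cog-1, die-1 and che-1. Alternatives covered stronger peaks alone, each replicate alone, other windows and overlap rules, the nearest gene, circular shifts, the ce10 build, and other windows and flanks for sequences. A further 5 were added after the data were seen.

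Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The methods were tested on simulated data. A list given summits at 60% of its genes passed in 20 of 20 runs with 4218 simulated summits, while 5 of 540 tests of the other lists passed. The remaining simulated summits were drawn at random over the genome and not at promoters. These runs therefore do not show how often lists pass falsely with the real summits. A 6-mer placed at 15% of 4218 random sites ranked 1 among all 6-mers, with 24 6-mers past the threshold in all. These sites were drawn at random over the genome, whereas GC content was 45.1% near real summits and 35.2% in their flanks. The 6-mer run therefore does not show how often 6-mers pass falsely with the real summits. A planted overlap of 59.3% was measured as 60.3%, and a planted correlation of 0.71 as 0.70.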

Results

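LSY-2 is a zinc finger transcription factor of the nematode Caenorhabditis elegans, known for its part in the left/right asymmetry of the ASE taste neurons. Its binding was measured by ChIP-seq in whole L1 larvae of strain OP367, which carries an eGFP-tagged lsy-2 transgene together with a wild-type unc-119 marker gene. The labels give 1 group with 2 biological replicates, so the data describe where the tagged protein was found and how far the replicates matched. They hold no comparison between conditions. Peak coordinates are those of the ce11 build. The signal of a peak is the authors' own value, and sequencing depth is unknown because the peak lists hold no read counts.

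The highest signal of all, 10307, stood at rpl-3, a large ribosomal subunit protein gene, on chromosome III from 3867310 to 3867833, with the summit in intergenic sequence 282 bp upstream of the transcript start. There the replicates had signals of 5871 and 4502, a mean of 5186 ± 968 (SD, n = 2). The next peaks were at the promoter shared by Y17G9B.5 and rpl-20 on chromosome IV (4749815 to 4750306, pooled signal 10070, replicate mean 5058 ± 1036, SD, n = 2) and at that of K11H12.8 and rpl-15 on chromosome IV (654671 to 655194, pooled signal 8593, replicate mean 4316 ± 864, SD, n = 2). The gene for cytochrome c oxidase subunit cox-5A on chromosome III followed (12904956 to 12905446, pooled signal 8244, replicate mean 4146 ± 910, SD, n = 2).

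Further down the 20 strongest peaks stood F55A11.1 and syx-5 (pooled signal 6750), Y55F3AR.2 and the chaperonin gene cct-8 (6085), ifet-1 and rps-1 (5833), cap-2 and gmps-1 (5563), and nra-2 with lin-53, a histone-binding protein gene (5071). Below these came ekl-4 and rps-20 (4877), Y25C1A.8 (4556), cct-1 and mig-5 (4469), lin-9, a member of the DREAM complex (3886), cup-14 and ndub-8 (3517), serp-1.1 (3437), atp-1 and mcrs-1 (3019), the elongation factor gene eef-2 with clsp-1 (3001), wdr-46 (2907), unc-16 (2783) and cbp-1 (2711). All 20 summits lay in a protein-coding promoter window, 18 in intergenic sequence and 2 inside a non-coding gene. In 5 of the 20 the window belonged to a ribosomal protein gene. Replicate 1 had the higher signal at 20 of these 20 peaks and at 3248 of the 4179 peaks past the IDR threshold with a summit in both replicates. Its level was higher across regions with such a peak (median log2 ratio to replicate 2 of 0.338). The signals were not scaled, so these counts and the SDs above include that offset.

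The replicates placed their strongest peaks at largely the same sites. Of the 4218 strongest peaks of replicate 1, 3378 (80.1%, 95% exact Clopper-Pearson interval 78.8 to 81.3) overlapped 1 of the 4218 strongest of replicate 2. Random circular shifts of replicate 2 along each chromosome gave a mean of 2.54% and at most 3.34% (permutation p = 0.001, one-sided, the smallest 1000 shifts can give). Across 15156 regions called in both replicates, signals had a Spearman rho of 0.73 and a Pearson r of 0.87 on the log2 scale. In regions overlapping a peak past the IDR threshold, rho was 0.83 over 4141 regions. These correlations are across peaks, which are not independent replicates, so no p-value is attached to them. The IDR list was made from these same replicates. Its length of 4218 and its regions are therefore not independent of how far the replicates matched. Among all peaks before IDR the overlap was 58.2%.

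**Figure D1:**
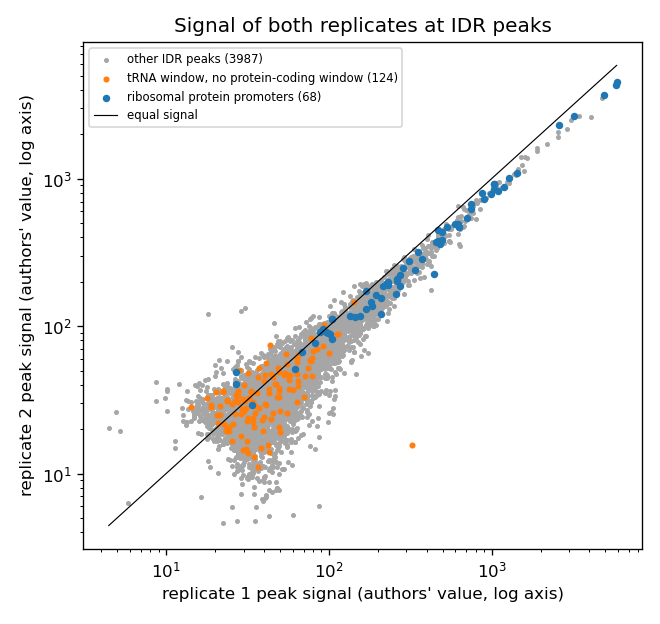
Signal of replicate 1 (x axis) and replicate 2 (y axis) at peaks past the IDR threshold, both in the authors' units on log axes, with a line of equal signal. Each point is a peak; the strongest ribosomal protein promoter, rpl-3, has 5871 in replicate 1 and 4502 in replicate 2.

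The authors' IDR threshold left 4218 peaks. Each was among the 4218 strongest of the 30000 pooled peaks, so the threshold lay at a signal of 42.2, and the −log10 q value was at its ceiling of 4.16 for 100% of them. The same reads on the ce10 build gave 4217 peaks. By chromosome, the ce11 set had 813 peaks on I, 685 on II, 833 on III, 690 on IV, 603 on V and 594 on X.

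Summits gathered just upstream of genes. A window from 1000 bp upstream to 200 bp downstream of an annotated transcript start held 3185 summits (75.5%, 95% exact interval 74.2 to 76.8), against a mean of 37.7% in circular shifts (permutation p = 0.002, two-sided, the smallest that 1000 shifts can give). With protein-coding genes alone the share was 63.0% against 26.0% (permutation p = 0.002). The median summit lay 192 bp upstream of the nearest protein-coding transcript start, and 40.4% of summits lay within 300 bp upstream. Coding exons held 42 summits (1.00%, against 24.5% in the shifts), introns 893 (21.2% against 34.3%) and 5' UTR exons 156 (3.70% against 1.76%). Intergenic sequence held 2814 (66.7% against 32.4%), and each of these differences had a permutation p of 0.002. The windows of 2 protein-coding genes met at 828 summits, as at rpl-20 and Y17G9B.5.

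**Figure D2:**
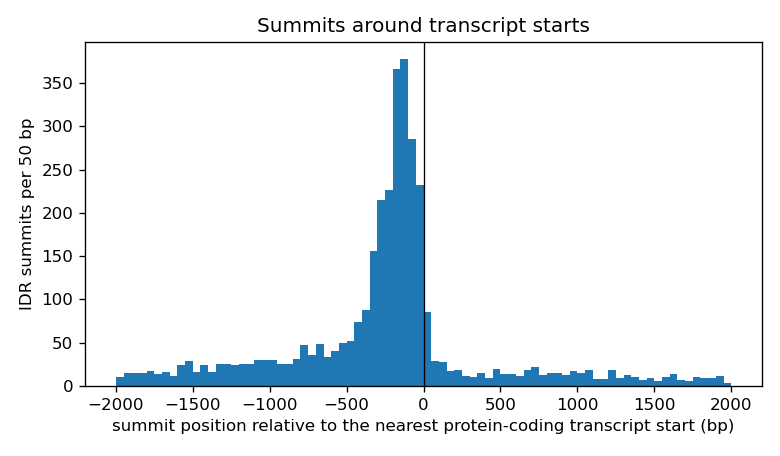
Position of peak summits past the IDR threshold (y axis, summits per 50 bp) relative to the nearest protein-coding transcript start (x axis, bp, negative upstream). Most summits gather upstream of the start, with a median of 192 bp upstream over all 4218 summits.

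In all, 4933 annotated genes had a promoter peak, among them 3385 of 19973 protein-coding genes (16.9%, 95% exact interval 16.4 to 17.5). Genes for ribosomal proteins stood far above that share. Of 78 genes for cytosolic ribosomal proteins, 71 had a promoter peak (91.0%, 5.46 times the share of other protein-coding genes, Fisher's exact adjusted p = 1.05e-45). Their examples are rpl-3, rpl-20, rpl-15 and rps-1. The median signal of the strongest peak at such a gene was 518, against 120.5 over all protein-coding genes with a promoter peak. Respiratory chain genes had peaks at 17 of 22 members (77.3%, ratio 4.58, Fisher's exact adjusted p = 5.88e-09), with cox-5A, atp-1, cox-5B (pooled signal 2182) and nuo-1 (879) the strongest. The nuo-1 peak lies in a window shared with rpl-36.A and counts for both lists. When each summit was given to the nearest protein-coding start alone, the ratios fell to 3.23 for ribosomal proteins and 3.44 for the respiratory chain (Fisher's exact adjusted p = 4.65e-13 and 4.61e-05). Under circular shifts, which keep neighbouring genes together, both lists still passed (adjusted permutation p = 0.0186 for ribosomal proteins and 0.028 for the respiratory chain), with mean ratios of 1.01 and 1.05 in the shifts.

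Chromatin, cell cycle, Hox and pan-neuronal genes also had more peaks by Fisher's exact test, but not by shifts. Chromatin regulators had peaks at 17 of 29 members (58.6%, ratio 3.47, Fisher's exact adjusted p = 2.31e-06), led by lin-53, lin-9, lin-54 (pooled signal 1089) and mes-2, a histone methyltransferase of the Polycomb type (323). The lin-54 peak is also that of rpl-12, whose start is nearer, and the start of nra-2 is nearer to the lin-53 summit. Cell cycle genes had them at 18 of 34 (52.9%, ratio 3.14, Fisher's exact adjusted p = 6.17e-06), led by the replication genes orc-1 (880), pcn-1 (616) and cdc-6 (531) and by efl-1, an E2F factor (485), although the starts of dhs-11 and acin-1 lie nearer to the summits of orc-1 and cdc-6. Hox genes and cofactors had them at 6 of 11 (54.5%, ratio 3.22, Fisher's exact adjusted p = 0.0106), including ceh-20 (182), unc-62 (143), lin-39 (118.6) and ceh-13 (114). Pan-neuronal function genes had them at 11 of 27 (40.7%, ratio 2.41, Fisher's exact adjusted p = 0.00694), including unc-108 (273), ric-19 (174), snb-1 (116.5) and the kinesin gene unc-116 (106). Under circular shifts these 4 lists had adjusted permutation p of 0.154, 0.112, 0.517 and 0.684 in that order. The mean ratios in the shifts were 1.33, 1.13, 1.53 and 1.53 and the middle 95% of shifts reached 3.14, 2.69, 4.81 and 3.30, so the ratios of Hox and pan-neuronal genes lay within that range. The Hox ratio fell to 1.32 with the narrower window of 500 bp upstream to 100 bp downstream (2 of 11, 18.2%, 95% exact interval 2.28 to 51.8, Fisher's exact adjusted p = 0.765). It was 2.70 without replicate 2, with 1 gene fewer (5 of 11, 45.5%, interval 16.7 to 76.6, Fisher's exact adjusted p = 0.051). The pan-neuronal ratio was 2.02 with the 2109 strongest peaks (6 of 27, 22.2%, interval 8.62 to 42.3, Fisher's exact adjusted p = 0.196). The Hox ratio was also lower with the window of 2000 bp upstream (2.56) and with any overlap (3.07), both still past the threshold by Fisher's exact test. Some other alternatives raised the Hox and pan-neuronal ratios. With the nearest start they were 3.70 for Hox (7 of 11) and 4.54 for pan-neuronal genes (21 of 27; Fisher's exact adjusted p = 0.00188 and 4.65e-11). Pan-neuronal genes had 2.96 with the window of 2000 bp upstream (17 of 27, 9.86e-06 by Fisher's exact test). Isolated Hox genes, an alternative added after the data were seen, had 6.27 (5 of 8, Fisher's exact adjusted p = 0.00241). Over all alternatives the ratios spanned 3.23 to 8.14 for ribosomal proteins, 3.44 to 6.01 for the respiratory chain, 2.61 to 4.73 for chromatin and 2.57 to 4.01 for cell cycle genes.

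Chemoreceptor and C-type lectin genes rarely had a promoter peak. Chemoreceptor genes had peaks at 10 of 1293 members (0.773%, ratio 0.0428, Fisher's exact adjusted p = 2.68e-89), among them srh-16 (456), sri-5 (430), srh-2 (207) and sre-1 (116.5), whose summit lies nearer to the start of B0495.9. C-type lectin genes had them at 5 of 240 (2.08%, ratio 0.122, Fisher's exact adjusted p = 1.25e-12). Both lists also passed under circular shifts (adjusted permutation p = 0.0186 for each, mean ratios in the shifts 0.696 and 0.827). By Fisher's exact test alone, shares were also lower for F-box genes (19 of 322, adjusted p = 1.86e-08), neuropeptide genes (5 of 140, 5.33e-06), collagens (9 of 156, 0.000179), sperm proteins (0 of 47, 0.000778), cytochrome P450 genes (3 of 74, 0.00394) and nuclear hormone receptors (29 of 269, 0.0106). Their adjusted permutation p under shifts lay between 0.0559 for neuropeptide genes and 0.54 for sperm proteins, cytochrome P450 genes and nuclear hormone receptors. Without replicate 1 the ratio went from 0.21 to 0.0837 for neuropeptide genes (2 of 140), from 0.339 to 0.49 for collagens (13 of 156) and from 0.239 to 0.398 for cytochrome P450 genes (5 of 74), all still past the threshold by Fisher's exact test. With the nearest start the neuropeptide ratio rose to 0.496 (12 of 140, Fisher's exact adjusted p = 0.00918). Over all alternatives the ratios spanned 0.0131 to 0.0761 for chemoreceptors, 0.0897 to 0.154 for C-type lectins, 0.25 to 0.647 for F-box genes, 0.231 to 0.49 for collagens, 0 to 0.247 for sperm proteins, 0 to 0.398 for cytochrome P450 and 0.402 to 1.08 for nuclear hormone receptors. An alternative added after the data were seen kept only genes with no other protein-coding start within 2000 bp. There the ratio was as low or lower with fewer genes tested for collagens (2 of 77, 0.258, exact interval of the share 0.316% to 9.07%), cytochrome P450 (1 of 49, 0.203, 0.0517% to 10.9%) and sperm proteins (0 of 11, 0% to 28.5%), with Fisher's exact adjusted p of 0.0557, 0.19 and 0.75. For F-box genes it rose from 0.344 to 0.647 (8 of 123, 2.85% to 12.4%, Fisher's exact adjusted p = 0.397), as the share of other genes fell from 17.1% to 10.1%. The ratio for nuclear hormone receptors, 0.633, rose above 1, to 1.08, when each summit was given to the nearest protein-coding start.

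**Figure D3:**
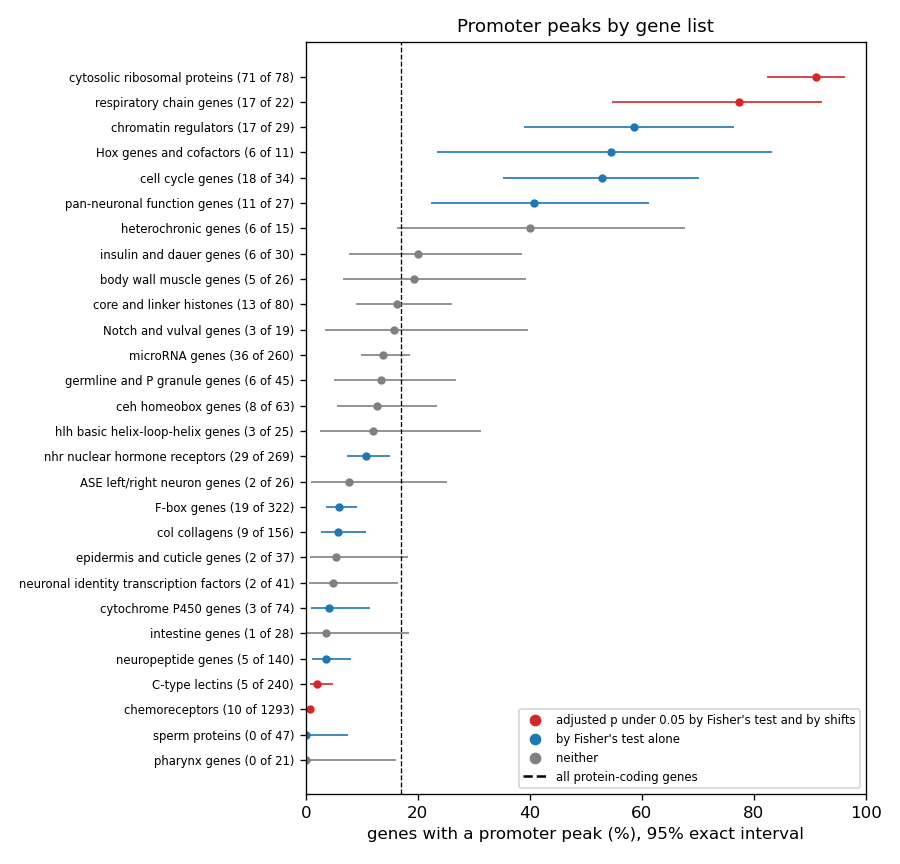
Share of genes with a promoter peak (x axis, %) in each of the 28 gene lists (y axis, with counts), with 95% exact intervals as bars. The dashed line marks all protein-coding genes (16.9%), and red marks the 4 lists that passed by Fisher's exact test and by shifts, from chemoreceptors (0.773%) to ribosomal proteins (91.0%).

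The other 14 lists did not pass. Among tissue lists, peaks stood at 5 of 26 body wall muscle genes (Fisher's exact adjusted p = 0.853), at 1 of 28 intestine genes, erm-1 (0.112), at 0 of 21 pharynx genes (0.0614), at 2 of 37 epidermis and cuticle genes, bli-6 (in a window shared with hrpf-2, whose start is nearer) and elt-1 (0.112), and at 6 of 45 germline and P granule genes (0.805). Neuronal identity transcription factors had them at 2 of 41, unc-42 and egl-44 (0.0614). Heterochronic genes had them at 6 of 15 protein-coding members (0.0551), among them lin-28 (pooled signal 286), lin-66, lin-46 (13 bp upstream of R186.8, whose start is nearer) and myrf-1. The lists for insulin and dauer (6 of 30), Notch and vulva (3 of 19), histones (13 of 80), ceh homeobox (8 of 63), hlh (3 of 25) and microRNA genes (36 of 260) had adjusted p of 0.763, 1, 1, 0.636, 0.853 and 0.118. Some of these lists passed Fisher's exact test in alternatives, and none passed under circular shifts. For neuronal identity, epidermis and cuticle, intestine and pharynx genes, among others, the range of ratios in the shifts began at 0. No low share of these lists could therefore pass by shifts, so the shifts cannot decide on their low shares. Neuronal identity factors, with a lower share, passed with the 2109 strongest peaks (Fisher's exact adjusted p = 0.0401), without replicate 1 (0.0207), with the window of 500 bp upstream (0.0104) and with any overlap (0.0429). Epidermis and cuticle genes, also lower, passed without replicate 1 (0.0274). With higher shares, microRNA (8.41e-05), heterochronic (5.59e-05) and body wall muscle genes (0.0279) passed with the window of 2000 bp upstream. The microRNA share there, 23.1%, was set against 13.6% of all other genes, which include 15363 piRNA genes with few peaks. In the main setting the microRNA share of 13.8% lay below the 16.9% of protein-coding genes. MicroRNA genes also passed with any overlap (0.0155), and in 2 alternatives added after the data were seen in which the share of other genes fell from 10.5%: to 6.84% with isolated protein-coding genes alone (0.000596) and to 8.99% with peaks away from small RNA genes (0.0306). Heterochronic genes passed in the latter as well (0.0422). With the nearest start, heterochronic (8.1e-07), insulin and dauer (0.00188) and muscle genes (0.0148) passed.

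The genes of the ASE neurons did not stand out. Of 26 protein-coding members, lsy-12 (pooled signal 135) and unc-37 (107) had a promoter peak (2 of 26, 7.69%, Fisher's exact adjusted p = 0.395). No promoter peak past the IDR threshold was found at lsy-2 itself (chromosome X, 2089704 to 2093256), the microRNA gene lsy-6 (V, 10647232 to 10647304), cog-1 (II, 14902493 to 14907533), die-1 (II, 10061302 to 10067917) or che-1 (I, 6517529 to 6520918). The nearest summit past the threshold was 14321 bp from lsy-6, 45394 bp from cog-1, 16063 bp from die-1 and 11188 bp from che-1. ASE neurons are few among the cells of a whole larva, and no sample was split by cell type.

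Peaks were sparsest on chromosome V, sparse on X, and densest on III and I. V had 14.3% of peaks on 20.9% of the genome length (ratio 0.685, exact binomial adjusted p = 3.35e-27), III a ratio of 1.44 (2.19e-26) and I of 1.28 (1.93e-13), while II and IV did not pass (0.0719 for each). This comparison of all 6 chromosomes was added after the data were seen, and that of X was planned. X had 594 peaks, 14.1% (95% exact interval 13.05 to 15.17) against 17.7% of the genome length (ratio 0.797, exact binomial p = 3.75e-10). Against its 13.7% of protein-coding genes the difference was not detected (ratio 1.03, exact binomial p = 0.433), while promoter peaks stood at 11.3% of X genes and 17.8% of autosomal genes (Fisher's exact p = 9.36e-19), with 10.3% on V. The middle 33.3% of each autosome held 1587 of 3624 autosomal peaks (43.8%, ratio 1.31, exact binomial p = 4.56e-39). The binomial tests treat peaks as independent, which neighbouring peaks are not.

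Of 2080 canonical 6-mers (a 6-mer and its reverse complement counted together), 736 were more frequent within 50 bp of summits than in flanks 300 bp away and 622 less frequent (Fisher's exact test, Benjamini-Hochberg adjusted). GAGAGA occurred near 28.7% of summits and in 6.19% of flanks (Fisher's exact adjusted p = 1.32e-170), and GACGCA near 17.4% and in 1.66% (adjusted p = 5.43e-150). ACCGTA, rank 138 by p, occurred near 7.73% and in 2.56% (Fisher's exact adjusted p = 1.30e-26). These 3 sequences were picked after the values were seen, and ACCGTA gathered at the 1406 strongest peaks (15.8% against 1.99% of their flanks), with 3.84% against 2.92% at the 1406 weakest. GC content was 45.1% near summits, 35.2% in the flanks and 35.4% in the genome.

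**Figure D4:**
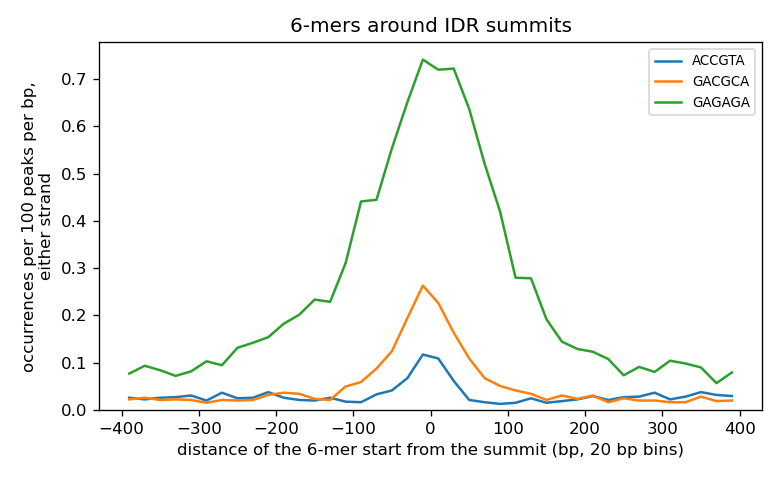
Occurrences of GAGAGA, GACGCA and ACCGTA on either strand per 100 peaks per bp (y axis) by distance from the summit (x axis, 20 bp bins). Each curve is highest in the bin centred 10 bp before the summit, at 0.741, 0.263 and 0.117.

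At the tagged gene the native locus showed no peak. No peak of any list lay within 20 kb of lsy-2. Of 1000 random protein-coding genes of X, 5.9% had none in the pooled list, 4.8% in that of replicate 1 and 3.6% in that of replicate 2. The pooled list left 66456 bp between its nearest summits on either side. Around unc-119 (chromosome III, 10902641 to 10908935) there were 18 pooled peaks within 20 kb, with a median of 18 at random genes of the chromosome. Between the ends of unc-119 the pooled list held 9 peaks, and 20 of 1722 other protein-coding genes of 5 to 8 kb (1.16%) held as many. Those with signals of 71.7, 47.3 and 44.5 were past the IDR threshold of 42.2, with 0 such peaks in the promoter window of unc-119. This gene is also a member of the pan-neuronal list.

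**Figure D5:**
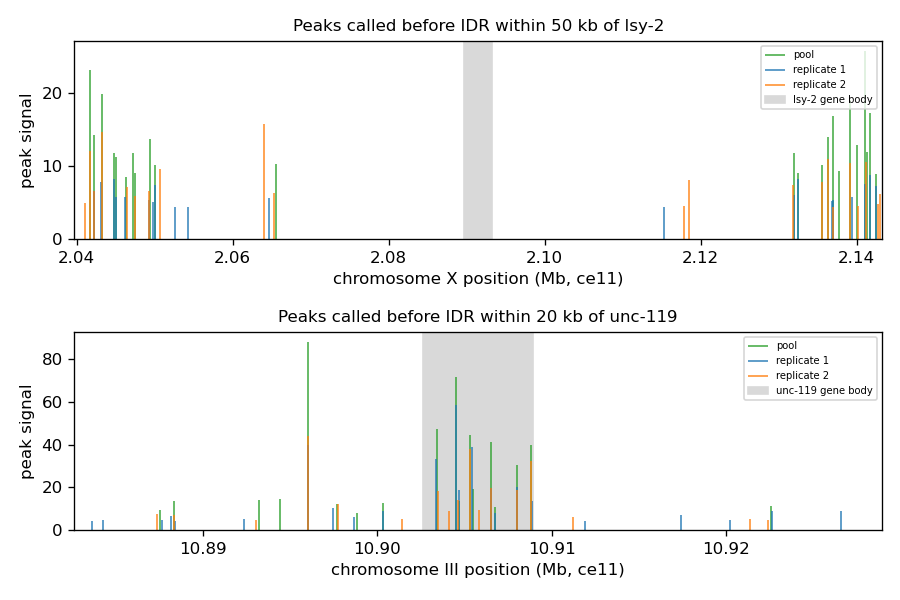
Peaks called before IDR by position (x axis, Mb, ce11) and signal (y axis, the authors' units) within 50 kb of lsy-2 and within 20 kb of unc-119, with gene bodies shaded. The pooled list has 0 peaks within 20 kb of lsy-2 and 9 between the ends of unc-119.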

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

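Tests of replicate 2 as the base, of protein-coding genes alone, of isolated genes, of peaks away from small RNA genes and of matched promoters were chosen after the data were seen. No paired analysis was possible because the labels give 1 group. The promoter share and the ratios of X and of the mid-chromosome to their length kept their direction and side of the threshold with stronger peaks and with each replicate alone, and the count of enriched 6-mers stayed between 638 and 736. Against its share of genes instead of length, no difference was detected for X (ratio 1.03, exact binomial p = 0.433), while 11.3% of X genes and 17.8% of autosomal genes had a promoter peak. Replicate overlap of 80.1% was 71.3% with 50% reciprocal overlap, 76.2% with summits within 100 bp, 84.8% among the 2109 strongest peaks and 58.2% among all peaks before IDR. Spearman rho was 0.83 in regions with an IDR peak. Keeping the 2109 strongest IDR peaks left 2942 genes with a promoter peak. Lists past the threshold fell from 14 to 4 with circular shifts and were 10 to 17 in the other alternatives. The shifts keep clusters of neighbouring genes together, but they also move summits off promoters. Protein-coding windows held 63.0% of the real summits and a mean of 26.0% in the shifts. Ranges under shifts were wide for small lists, as with 0 to 4.81 for Hox genes. The fall from 14 to 4 can therefore not be assigned to gene clusters alone, and its cause was not tested further. The shifts could not have passed a low share for sperm proteins, cytochrome P450 genes or any other list whose range began at 0. Within 50 kb of lsy-2 the pooled list held 23 peaks, against 0 within 20 kb. Among 279 list values, 231 kept direction and side, 17 lost the threshold, 15 passed it and 16 changed direction.

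Ratios of shares that changed direction were these. With the strongest peaks: germline 1.01, insulin 0.605, hlh 1.09. Without a replicate: histones 1.11 to 1.33. With the narrow window: insulin 0.725, histones 1.09. With the nearest start: neuronal identity 1.13, Notch 1.84, nuclear hormone receptors 1.08. With isolated genes: ASE 1.18, Notch 1.88, histones 1.67, ceh 1.14, hlh 1.58, nuclear hormone receptors 1.03. The cause was not tested. The nearest-start rule gives microRNA genes no value. Read depth was unknown and limits every count of peaks to an unknown degree.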

Other observations

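The gene families, gene types, below-threshold peaks, signal ranks, matched promoters, tRNA and locus tests in this part were chosen after the pattern they address was seen, although the bounds of the promoter, tRNA and locus tests were written before their values were known.

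Of 175 families of 10 or more protein-coding genes with a shared name, 0 passed under circular shifts, while 30 were higher and 36 lower by Fisher's exact test. With 1000 shifts no family can reach a p below 0.002, and the 4 that reached it, rpl (41 of 47), rps (30 of 31), str (0 of 193) and clec (5 of 240), had an adjusted permutation p of 0.0874, so this test of 175 families could not pass them. Further examples by Fisher's exact test, each followed by its adjusted permutation p under shifts, are these. Nucleoporin genes (npp) had a promoter peak at 19 of 26 members (73.1%, Fisher's exact adjusted p = 1.22e-08, shifts 0.175) and translation initiation factor genes (eif) at 18 of 25 (72.0%, 4.56e-08, shifts 0.175). Mitochondrial ribosomal protein genes had them at 21 of 41 (mrpl, 51.2%, 7.33e-06, shifts 0.194) and 16 of 29 (mrps, 55.2%, 4.19e-05, shifts 0.175), and proteasome regulatory subunit genes (rpn) at 10 of 13 (76.9%, 4.19e-05, shifts 0.242). Ligand-gated channel genes (lgc) and irld genes had them at 0 of 56 each (0.00033, shifts 0.66 and 0.692). Their share of 0 is the lowest possible, and its unadjusted permutation p was 0.136 and 0.184. No low share of these families could therefore pass by shifts.

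Small nucleolar RNA genes had peaks at 133 of 346 (38.4%, 95% exact interval 33.3 to 43.8) and snRNA genes at 27 of 129 (20.9%, 14.3 to 29.0), with adjusted permutation p of 0.0044 and 0.0403 under shifts. Those away from protein-coding starts were not tested, so summits of neighbouring protein-coding promoters stay open as a source. Without the 337 peaks with a tRNA, snoRNA or snRNA start in reach, ribosomal protein genes with a peak went from 71 to 57 of 78. Genes for piRNAs had them at 281 of 15363 (1.83%) and pseudogenes at 42 of 2128 (1.97%), both lower (adjusted permutation p = 0.0044 for each).

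The 25782 pooled peaks below the IDR threshold lay in protein-coding promoter windows at 29.1%, against 25.9% in circular shifts (ratio 1.12, permutation p = 0.002).

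Genes for tRNAs carried IDR peaks at 186 of 612 (30.4%, 95% exact interval 26.8 to 34.2), against 16.9% of protein-coding genes. Neighbouring protein-coding promoters cannot be the whole source, since the 239 tRNA genes with no protein-coding start within 2000 bp had peaks 5.85 times as often as in shifts (26.8% against 4.58%, permutation p = 0.002). ACCGTA or GACGCA, picked from summits mostly at protein-coding promoters, occurred at 6.40% of tRNA-only summits and 19.2% of signal-matched protein-coding ones (ratio 0.333, Fisher's exact p = 0.00394), while for GAGAGA, at 24.8% and 32.8%, no difference was detected (ratio 0.756, Fisher's exact p = 0.209), so a sequence in common stays open. Reads shared between identical copies stay open as a candidate explanation, since tRNA genes with an identical copy had peaks 1.80 times as often as unique ones (33.9% against 18.9%, the latter with an interval of 12.8 to 26.3 that holds the protein-coding share, Fisher's exact p = 0.000578). Fisher's exact test of the copies treats tRNA genes as independent, although neighbouring ones can share a summit. The design names no second group, so no biological explanation was tested.

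The summit sequences differed with signal. ACCGTA occurred at 15.8% of the 1406 strongest IDR peaks and 3.84% of the 1406 weakest (Fisher's exact p = 9.06e-28), and GACGCA at 21.5% and 13.4% (p = 1.72e-08), while GAGAGA occurred at 23.8% and 30.01% (p = 0.000253). ACCGTA was 3.54 times and GAGAGA 3.43 times as frequent near summits as at matched places in promoters without a peak (Fisher's exact p = 2.37e-27 and 6.13e-68). GACGCA, for which no bound was written, was 9.44 times as frequent (18.9% against 2.00%, Fisher's exact p = 1.33e-99). The places were matched by distance from the start and not by base composition. All of these sequences were also picked from these same summits. The comparison therefore cannot decide on base composition, which stays open. The matched promoters differ from bound ones in more than the peak, so a direct contact with any of these sequences remains a hypothesis, untested here.

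A chance gap between peaks stays open for the lack of pooled peaks near lsy-2. Of the 2730 other protein-coding genes of X, 160 (5.86%, 95% exact interval 5.01 to 6.81) had no pooled peak within 20 kb. This lies close to the bound of 5%, and the replicate lists fall under it with 4.8% and 3.6% of random genes. Neighbouring genes share a gap, and the interval treats genes as independent, so it cannot place the pooled share above the bound. Near lsy-2 the peaks were missing from every list, and the share of genes with none in every list was not counted. That share cannot exceed the lowest share of a single list, so the pooled share cannot decide on a chance gap. Extra copies of unc-119 in the transgene stay open as a candidate explanation for the 9 pooled peaks in its body, which 1.16% of genes of similar length matched. That share shows how rare the count is and does not test its cause. The same transgene carries lsy-2, which had 0 peaks within 20 kb. Those 0 peaks cannot decide on extra copies either way. The sources used here do not give the strain of the control, and copy number was not analysed here.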
